A study of Bubalus bubalis with 2 samples.

How the data were processed

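Cell-free total RNA of saliva was measured by RNA sequencing in 2 Murrah buffalo samples, 1 taken at estrus and 1 at diestrus, and the stage of each sample was taken from its label. Per the labels' protocols, libraries were made with the Illumina TruSeq RNA kit, version 2. TopHat, Bowtie, Cufflinks and Cuffdiff were named, per the submitters' processing notes, and their versions and the genome build were not given in the sources used here. Per the file headers, the deposited table held an FPKM value for each of 20905 genes in each library, which the authors made from fragment counts scaled to transcript length and library size. Whether totals were rescaled between libraries was not given in the sources used here. The deposited log2 fold change was the log2 of diestrus over estrus, as checked on the 7344 genes above 0 in both libraries, which all matched within 0.001. The deposited p-value and q-value columns were made by the authors and were copied and not recomputed. The authors' column of calls matched an unadjusted p-value under 0.05 on all 20905 genes. The table had no column that says which genes were tested, so the 1253 genes with a p-value under 1 were taken as tested. The ratio of q-value to p-value of TIMP1 matches 1292 tests, and the q-value of ATP6 matches rank 36 where the table gives rank 35, so some tested genes are not seen as such in the table.

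Identifiers in the table carry the Ensembl cattle prefix on 4910 rows, all described as pseudogenes, and chromosomes are numbered up to 29, as in cattle. Of the other 15995 symbols, 14361 are also in the buffalo RefSeq annotation of assembly NDDB_SH_1, which was used for names only. Coordinates are those of the table, printed counting from 1. Its starts were read as counting from 0, because the spans of 124 of 134 olfactory receptor loci, mostly intronless coding regions, were multiples of 3 on that reading. Loci can be merged spans, and 1830 rows share a locus with another row, so neighbouring or overlapping genes can share reads. Mapping to another species' genome, close paralogs and pseudogenes can all move a gene's FPKM, and an exact 0 can be a failed estimate.

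With 1 library per stage no test of the stages was possible, so no p-values were computed. The ratio of each gene was log2((estrus FPKM + 1)/(diestrus FPKM + 1)), with a pseudocount of 1 FPKM, which understates the change of low genes. A gene was counted when its mean FPKM over both libraries was at least 1, which 8269 genes met, and was called apart at 2-fold or more. For each gene list with at least 3 counted members, the median ratio was placed among 10000 random lists of the same size drawn from the counted genes and matched on mean expression in 20 bins, and a percentile under 2.5 or over 97.5 was described as outside the random range. Such a percentile describes these 2 libraries and is not a test of the stages. The lists, the rule for named genes, the filter and the alternatives were set before the data were examined. The lists covered salivary gland secreted proteins, oral squamous epithelium, neutrophils, macrophages and monocytes, lymphocytes, erythroid cells, fibroblasts and extracellular matrix, mitochondrially encoded genes, metalloproteinases and their inhibitors, estrogen-responsive genes, steroid receptors and steroidogenesis, heat shock and chaperone genes, Toll-like receptor signalling, inflammatory cytokines and the NF-kB response, interferon-stimulated genes, cell proliferation, taste and odorant binding, common reference genes, cytosolic ribosomal proteins, nuclear-encoded respiratory chain subunits, MHC class I and II, microRNA genes and histone genes. Some genes are in more than 1 list, such as RPLP0, B2M and SDHA, which are also reference genes.

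Named genes were TIMP1 and any mir-141 gene, and then, among genes with a symbol, a mean of at least 10 FPKM and a value above 0 in both libraries, the 10 highest and the 10 lowest ratios. They also included the 5 genes of highest value among those at 0 in the other library, for each library, the 5 genes of highest value in each library, and up to 4 counted members of highest mean from each list. Genes named outside this rule are said to have been chosen after their values were seen, or are members that a count of a list singles out.

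The depth of each library was recovered from the FPKM values of loci spanning 400 to 3000 bp. The worth of 1 fragment was the step at which the most loci lay within 0.5% of 1 to 3 fragments, with 40 such loci in estrus and 107 in diestrus where other steps gave a median of 2. On simulated libraries with known steps the error was at most 0.389%. A second estimate came from the steps among the log2 ratios of genes above 0 in both libraries, where 235 genes lay on the best shift against a median of 64 on other shifts. Because the effective length of spliced genes is unknown, no counts per gene were computed. The list placement was tested on simulated lists drawn from the 8269 counted genes, of which 7% lay outside the random range with no shift, 41% with a shift of 1 log2 unit and 79% with a shift of 2. Exact 95% binomial intervals in the closing section describe shares of genes, with genes treated as independent draws. They cover neither the counting error of fragments nor the spread between animals. The comparison of keratins with other epithelial genes was tried with 3 reference sets after its values had been seen. Of 6 genes, 4 lay above all 15 lower keratins, 6 above the upper quartile of all 17 keratins and 2 above all 16 keratins other than KRT6A, and the last set, which leaves out only KRT6A, was used.

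The alternatives were pseudocounts of 0.1 and 10 FPKM, no filter, a mean of at least 10 FPKM, only genes with an authors' p-value under 1, only genes above 0 in both libraries, a 4-fold limit, random lists without matching, the mean in place of the median of a list, a q-value of at most 0.01 for the authors' calls, and 3 rescalings of the diestrus library. The rescalings set the median log2 ratio to 0, made the upper quartiles equal, or made the sums equal after the 20 leading genes of each library were left out. A mean of at least 50 FPKM and lists without keratins were added after the data had been seen. Values at a mean of at least 100 FPKM were also not among the alternatives set before. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Sequence reads and transcript isoforms were not analysed here.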

Results

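Total RNA of the cell-free fraction of saliva was sequenced from Murrah water buffalo, a river-type dairy breed, with 1 library from estrus, the stage of sexual receptivity, and 1 from diestrus, the luteal stage of the cycle. The deposited gene table listed 20905 genes with an FPKM value (fragments scaled to transcript length and to the number of fragments mapped) in each library. In the estrus library 8424 genes were above 0 and in the diestrus library 9491 were, of which 7344 were above 0 in both, while 10334 genes were listed at 0 in both. With 1 library per stage, no spread between animals can be estimated, so the differences below have no replicate check and describe these 2 libraries.

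The values themselves show how deeply each library was read. On short loci the FPKM values lay on steps that stand for whole fragments, and 1 fragment on 1 kb of effective length was worth 0.233 FPKM in the estrus library and 1.25 FPKM in the diestrus library. A fragment thus counted 5.37 times as much in diestrus as in estrus, and the steps among ratios of genes above 0 in both libraries gave 5.38, so by the authors' scaling the estrus library was the deeper by that factor. If each denominator was the library's own total, the steps correspond to 4287622 fragments in estrus and 799101 in diestrus, although the authors' tool can rescale totals between libraries, so the absolute depth is not known. A transcript of 1 kb reached 3 fragments at 0.6997 FPKM in estrus and at 3.75 FPKM in diestrus. Values in the diestrus library under that level rest on fewer than 3 fragments per kb.

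The comparison of estrus with diestrus addresses which salivary transcripts differ between the stages, and the series title puts forward TIMP1 and a predicted mir-141 as markers. TIMP1, the secreted inhibitor of matrix metalloproteinases on chromosome X (91232235 to 91236073), was among the most abundant transcripts of both libraries. It stood at 36054 FPKM in estrus and 2988 FPKM in diestrus, a log2 ratio of 3.59 or 12.1-fold on the log2(FPKM + 1) scale, which understates the change of low genes. The same scale is used for every ratio below. The FPKM values summed to 1016100 in estrus and 521566 in diestrus, and ratios are not corrected for this unless a rescaling is named. With equal upper quartiles the log2 ratio of TIMP1 was 3.30. In the authors' deposited table TIMP1 had the smallest p-value, 5e-05, and a q-value of 0.0646. No gene was named mir-141, and the 2 microRNA genes in the table were listed at 0 in both libraries. Whether these libraries can hold microRNAs was not checked, and mir-141 may have been measured in another way. The values here are therefore no test of mir-141 as a marker.

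A small number of rows held much of the FPKM in the estrus library. OPRM1, the mu-opioid receptor, was listed at 129018 FPKM against 83.0 FPKM in diestrus, and PPARGC1A, a coactivator of mitochondrial biogenesis, at 92833 against 116 FPKM. These genes together held 21.8% of all FPKM in the estrus library, whereas the 2 most abundant genes of the diestrus library held 9.50% of its smaller FPKM sum. What the reads under the values of OPRM1, PPARGC1A, TBX15 and CSPG5 in estrus come from was not checked, so these values are not read as expression of those genes. TIMP1 ranked next. KRT6A, a keratin of stressed and stratified epithelium on chromosome 5 (27558902 to 27564151), followed at 30046.5 against 323 FPKM with a log2 ratio of 6.53. MT2A, a metal-binding metallothionein on chromosome 18, stood at 20731 against 1084 FPKM with a log2 ratio of 4.26.

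The most abundant transcripts of the diestrus library came from mitochondria and from stress and iron-storage genes. ATP6, a mitochondrially encoded subunit of ATP synthase, stood at 34005 FPKM in diestrus and 2794 FPKM in estrus, a log2 ratio of -3.60. ND1, a mitochondrially encoded subunit of complex I, stood at 15537 against 7960 FPKM. The locus given for ATP6 spans positions 5687 to 14509 of the mitochondrial genome and is also the locus given for ND6, which has its own FPKM value. The locus given for ND1 spans positions 364 to 5374. Both can be merged spans, so the values of ATP6 and ND1 may not stand for single genes. HSPB1, a small heat shock protein, was lower in estrus at 4509 against 12318 FPKM in diestrus. FTH1, the ferritin heavy chain, stood at 9195 FPKM in estrus and 7581 FPKM in diestrus, and its log2 ratio of 0.28 turned to -0.019 once the upper quartiles of the libraries were made equal. The remaining gene of the leading 5, the pseudogene ENSBTAG00000009359 on chromosome 15, stood at 12584 FPKM in diestrus and 9042 FPKM in estrus.

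Among genes above 0 in both libraries, the largest ratios towards estrus belonged to TBX15, a T-box transcription factor of skeletal development, at 16097 against 2.17 FPKM with a log2 ratio of 12.31. OPRM1 followed with 10.59, PPARGC1A with 9.63 and MAFG, a small Maf transcription factor, with 9.22. GTF3A, which activates transcription of the 5S ribosomal RNA genes, was at 541 FPKM in estrus and 0.000182 FPKM in diestrus, with a log2 ratio of 9.08. The other members of the leading 10 were ICA1 (592 against 2.34 FPKM), ZNF821 (300.2 against 0.715 FPKM), RBM48 (568 against 3.20 FPKM), OGFOD2 (261 against 1.02 FPKM) and NAXE (452 against 2.96 FPKM). For 8 of these 10 genes the diestrus value lay under the level of 3 fragments per kb, so the size of the ratio is uncertain. The number of fragments per gene is not known. The diestrus value of GTF3A lay far under 1.25 FPKM, the worth of 1 fragment per kb, so its place in the ranking is not reliable.

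The largest ratios towards diestrus, again among genes with a symbol and above 0 in both libraries, belonged above all to keratins. KRT17, a keratin of basal and stressed epithelium on chromosome 19 (42472440 to 42484047), was listed at 0.174 FPKM in estrus and 1117 FPKM in diestrus, a log2 ratio of -9.90. KRT14 and KRT15, both keratins of basal epithelial cells, had log2 ratios of -7.64 and -7.46. KRT19 and KRT7, keratins of simple and ductal epithelium, had log2 ratios of -8.59 and -7.00. The other genes of the lowest 10 were THAP12 (0.640 against 474 FPKM), RSPH4A, a radial spoke protein of motile cilia (1.05 against 516 FPKM), NLGN1, a synaptic adhesion protein (0.478 against 253 FPKM), CHST6, a keratan sulfate sulfotransferase (0.206 against 185 FPKM), and ACTA1, the skeletal muscle actin (2.25 against 378 FPKM). In 8 of these 10 the estrus value lay under the level of 3 fragments per kb.

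Some genes with high values in 1 library were listed at 0 in the other. CSPG5, a proteoglycan of neural tissue on chromosome 22 (52649429 to 52661597), was listed at 11585.5 FPKM in estrus and at 0 in diestrus. PEBP4, THOC7, SNRNP25 and RABGGTB were listed at 373, 328, 289.9 and 262 FPKM in estrus and at 0 in diestrus. In the opposite direction ATOH7, a transcription factor of the retina, was listed at 889 FPKM in diestrus and at 0 in estrus. SLC32A1, the vesicular transporter of GABA, was listed at 431 FPKM in diestrus, the neurofilament gene NEFM at 309, the ribosomal protein gene RPS29 at 290.0 and SIX2, a transcription factor of kidney progenitors, at 241, all of them at 0 in estrus. The locus of RPS29 spans 171 bp, so its value can rest on few fragments. A listed 0 is not read as absence here, because 27 of the 82 rows for cytosolic ribosomal proteins, which every cell uses, were also at 0 in both libraries.

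**Figure D1:**
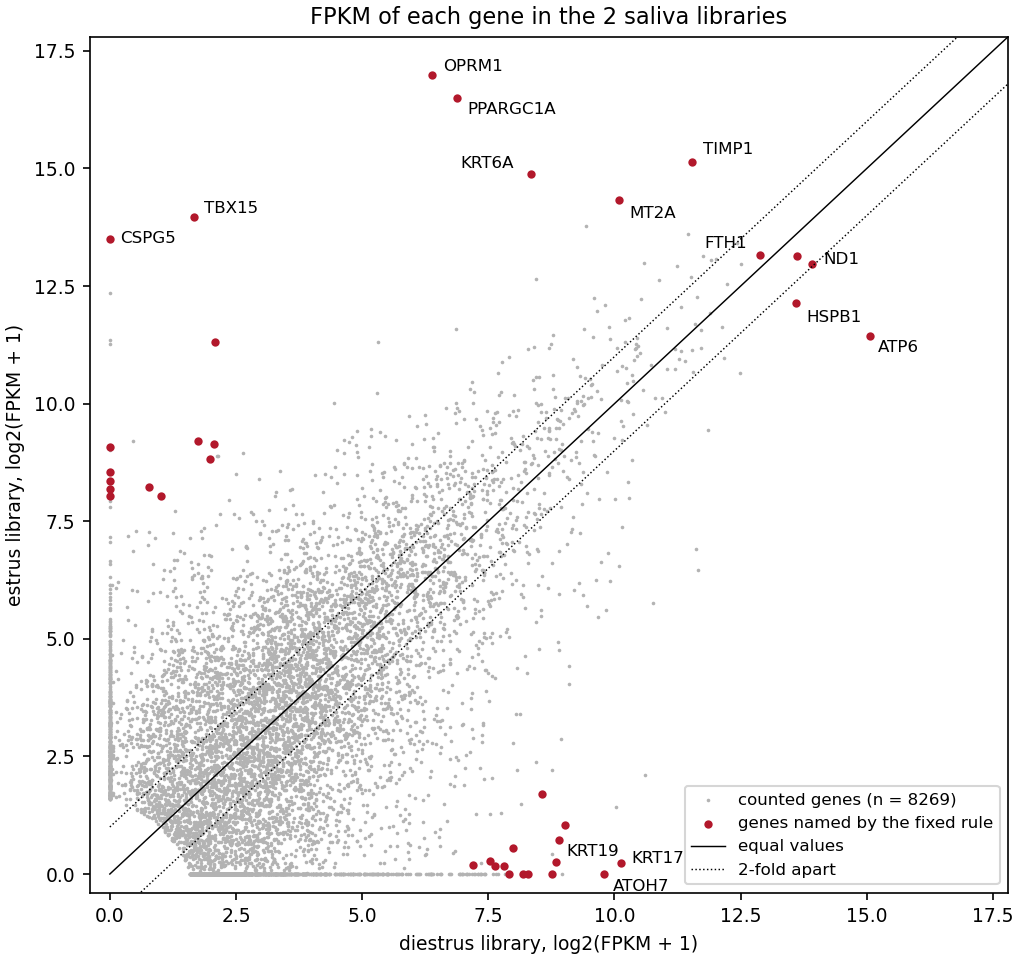
FPKM of the 8269 counted genes in the diestrus library (horizontal axis) and the estrus library (vertical axis), both as log2(FPKM + 1), with the genes named by the fixed rule in red, the line of equal values and the lines of a 2-fold difference on this scale. TIMP1 lies above the line at 36054 against 2988 FPKM, while KRT17 lies near the horizontal axis at 0.174 against 1117 FPKM.

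Genes of the oral squamous epithelium, the lining whose shed cells enter saliva, were lower in the estrus library. Of 20 counted members 15 were at least 2-fold lower, 3 were higher and 2 lay between, and their median log2 ratio of -2.13 lay below that of all 10000 random lists matched on expression. ECM1, an extracellular matrix protein of skin and mucosa, stood at 26.0 FPKM in estrus against 479 FPKM in diestrus, whereas SFN, an epithelial 14-3-3 protein, stood at 107 against 168 FPKM. KRT6A and the calcium-binding proteins S100A2 (119 against 4.34 FPKM) and S100A14 (50.9 against 19.98 FPKM) were the 3 members higher in estrus. Leaving out the keratins, an alternative chosen after the values were seen, left 13 members with a median of -1.74 at percentile 0.405.

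**Figure D2:**
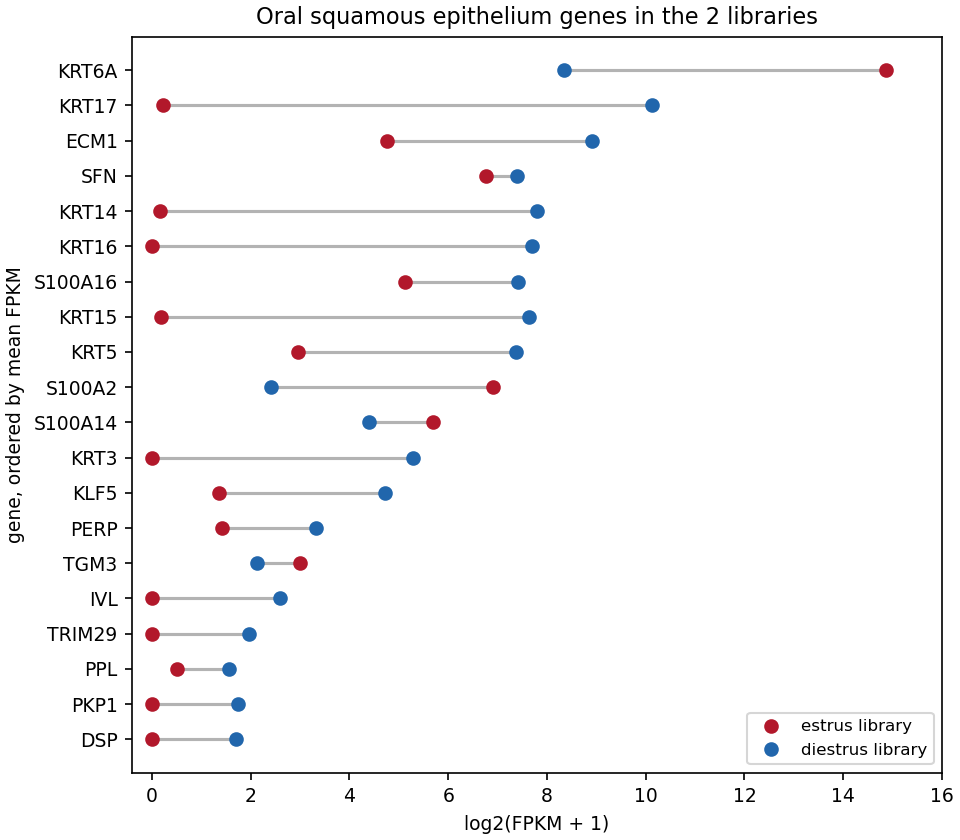
Values of the 20 counted genes of the oral squamous epithelium as log2(FPKM + 1) (horizontal axis), with the estrus library in red and the diestrus library in blue, 1 library each, ordered by mean FPKM. KRT6A lies higher in estrus at 30046.5 against 323 FPKM, while 15 of the 20 genes lie at least 2-fold lower.

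Estrogen-responsive genes were also lower in estrus as a group, with 13 of 26 counted members at least 2-fold lower, 6 higher and 7 between. Their median log2 ratio was -1.12, at percentile 0.320 of the random lists. The most abundant members were IGFBP4, a binding protein of insulin-like growth factors (1070.2 against 649 FPKM), THBS1, the adhesive glycoprotein thrombospondin (712 against 479 FPKM), FKBP4, a cochaperone of steroid receptors (382 against 176 FPKM), and KRT19 (0.193 against 460.1 FPKM). The list holds epithelial keratins, and without them the percentile was 2.02. Among genes above 0 in both libraries the direction turned, with a median of 0.64 at percentile 68.9. That filter left out 6 members at 0 in estrus and 0 members at 0 in diestrus, which raised the median of the list. The random lists were also drawn only from genes above 0 in both libraries, whose median was 0.13. The placement below the random range thus depended on these 6 listed zeros, and a listed 0 can be a failed estimate.

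Mitochondrially encoded genes were lower in estrus, with a median log2 ratio over 4 genes of -3.57 at percentile 0.240. CYTB, of complex III, stood at 92.2 against 1082 FPKM and ND6, of complex I, at 43.0 against 816 FPKM, so 3 of the 4 were at least 2-fold lower and ND1 lay between. ATP6 and ND6 share 1 locus, so reads can be split between them. That locus and the locus of ND1 can be merged spans, so the 4 rows may not stand for 4 single genes. All 6 counted MHC genes, which present antigens, were at least 2-fold lower in estrus, with a median of -2.43 at percentile 0.870. B2M stood at 234 against 657 FPKM, BoLA at 56.5 against 149 FPKM, BOLA-NC1 at 10.2 against 58.9 FPKM, and CD74 at 0 in estrus against 7.95 FPKM in diestrus. With only genes above 0 in both libraries the MHC percentile was 5.04, inside the central 95% of random lists. Here too the filter left out only members at 0 in estrus, 3 of the 6.

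Cell proliferation genes were higher in estrus, with 11 of 19 counted members at least 2-fold higher, 2 lower and 6 between, and a median log2 ratio of 1.25 at percentile 98.6. PLK1, a mitotic kinase, stood at 84.2 against 18.5 FPKM, and the replicative helicase subunits MCM3 and MCM7 at 38.3 against 1.39 FPKM and 42.8 against 22.6 FPKM. UBE2C, a ubiquitin-conjugating enzyme of mitosis, was among those lower in estrus, at 10.8 against 28.0 FPKM. For 12 of the 19 genes the diestrus value lay under the level of 3 fragments per kb. Cell proliferation was the only list above the random range, and 5 lists lay below it. If the genes of a list were unrelated, 1 of the 20 lists with a percentile would lie outside by chance. Genes of a list can vary together and some are in more than 1 list, so more lists can lie outside by chance.

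**Figure D3:**
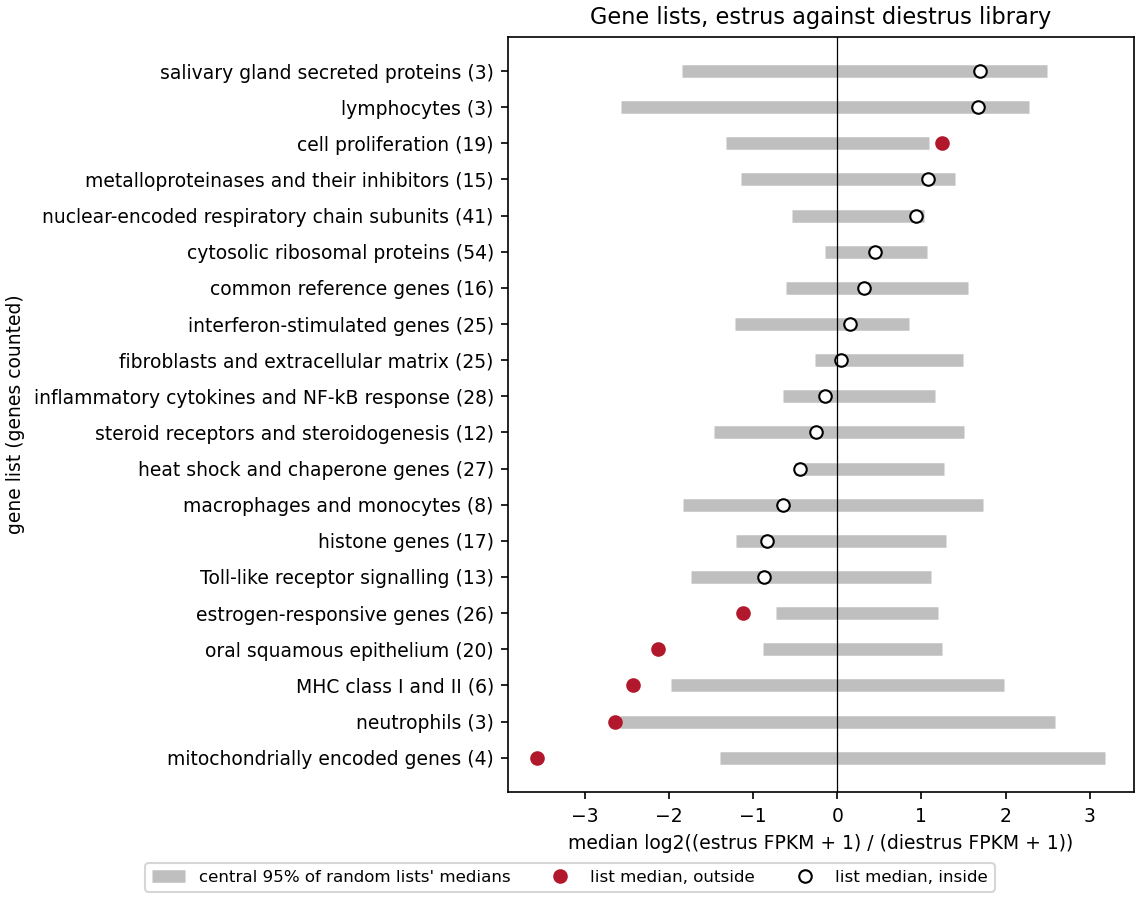
Median log2 ratio of estrus to diestrus (horizontal axis) of each of the 20 lists with at least 3 counted genes, with the number of genes counted in brackets. Grey bars span the central 95% of the medians of 10000 random lists matched on expression, filled red points lie outside and open points inside; cell proliferation lies above at 1.25 and mitochondrially encoded genes lie below at -3.57.

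Few of the marker genes of salivary glands and blood cells were listed above 0, which is not read as absence of those cells. For salivary gland secreted proteins 23 of 26 rows were at 0 in both libraries, and the 3 counted genes were CST6, a cystatin (4786 against 1471 FPKM), the protease inhibitor SLPI (19.3 FPKM in estrus, 0 in diestrus) and AZGP1 (0 in estrus, 2.37 FPKM in diestrus), at percentile 89.0. For neutrophils 36 of 40 rows were at 0 in both, and the 3 counted genes were the oxidase subunit CYBA (212 against 51.7 FPKM) and the calprotectin family members S100A9 and S100A12 (0 against 15.96 and 0 against 5.24 FPKM), with a median log2 ratio of -2.64 at percentile 1.17. This placement rests on 3 genes and was lost with no filter (29.0), with a pseudocount of 10 (7.66), with unmatched random lists (3.18) and with the mean of the list (11.3). Among 8 macrophage and monocyte genes 3 were higher, 3 lower and 2 between at percentile 21.2, with APOE at 36.1 against 233 FPKM and LGMN at 117 against 38.1 FPKM. The 3 counted lymphocyte genes were all higher in estrus at percentile 91.3, namely CD247, CD8B and POU2AF1, with CD247 at 115 against 1.62 FPKM. Of the erythroid genes 2 were counted, SLC25A37 (5.30 against 71.4 FPKM) and HBA (0.510 against 6.63 FPKM), and taste and odorant binding genes were listed at 0 in both libraries on all 16 rows.

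Fibroblast and extracellular matrix genes, by contrast, were above 0 in both libraries on all 25 rows, with medians of 561 FPKM in estrus and 404 FPKM in diestrus. SPARC, a collagen-binding matrix protein, stood at 3903 against 3815 FPKM and the intermediate filament VIM at 2014 against 4579 FPKM. The contractile genes TAGLN (8173 against 1536 FPKM) and ACTA2 (4394 against 902 FPKM) were higher in estrus. In all, 5 members were higher, 7 lower and 13 between, at percentile 8.60.

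Of the metalloproteinases and their inhibitors, the family of TIMP1, 8 of 15 counted genes were higher in estrus, 4 lower and 3 between, with a median of 1.08 at percentile 93.1, inside the random range. Without the filter on low values 23 genes were counted and the direction turned, with a median of -0.42 at percentile 31.7. TIMP2 stood at 4011 against 801 FPKM with a log2 ratio of 2.32, while TIMP3 (876 against 1318 FPKM) and the gelatinase MMP2 (1082 against 1126 FPKM) lay within 2-fold. Steroid receptor and steroidogenesis genes were divided, with 5 of 12 higher, 4 lower and 3 between at percentile 34.6. The mitochondrial translocator TSPO stood at 470 against 778 FPKM and the dehydrogenase HSD17B10 at 91.0 against 11.9 FPKM.

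The lists of heat shock, Toll-like receptor, inflammatory and interferon genes lay inside the random range. Heat shock and chaperone genes had 4 of 27 higher, 8 lower and 15 between at percentile 3.08, with HSPA1A at 1486 against 677 FPKM and CRYAB at 371 against 917 FPKM. Among genes above 0 in both libraries that percentile was 1.67, just outside. Toll-like receptor signalling had 2 of 13 higher, 5 lower and 6 between at percentile 22.2, with the kinase IRAK1 at 64.7 against 7.62 FPKM and the adaptor MYD88 at 23.5 against 23.5 FPKM. Inflammatory cytokines and the NF-kB response had 8 of 28 higher, 12 lower and 8 between at percentile 19.0, with the chemokine CCL5 at 1017 against 371 FPKM and IER3 at 954 against 117 FPKM. Interferon-stimulated genes had 10 of 25 higher, 6 lower and 9 between at percentile 71.7, with MX1 at 154 against 39.8 FPKM, ISG15 at 176 against 15.3 FPKM and IRF9 at 85.9 against 13.7 FPKM. With a mean of at least 10 FPKM, 11 interferon-stimulated genes remained counted, at percentile 99.9.

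Genes of general cell function also lay inside the random range. Nuclear-encoded respiratory chain subunits had 19 of 41 higher, 9 lower and 13 between at percentile 95.7, with COX6A1 at 1441 against 333 FPKM and UQCR10 at 1208 against 147 FPKM. Cytosolic ribosomal proteins had 17 of 54 higher, 17 lower and 20 between at percentile 40.4, with a median of 0.45 and a mean of -0.14, which differ in sign, and equal sums without the 20 leading genes turned the median to -0.080. RPL29 stood at 7823 against 2404 FPKM and RPS15 at 2671 against 960 FPKM. Histone genes had 3 of 17 higher, 8 lower and 6 between at percentile 6.70, with H2AFX at 321 against 192 FPKM. Common reference genes had 6 of 16 higher, 3 lower and 7 between at percentile 33.2, with ACTG1 at 8639 against 4122 FPKM and ACTB at 2329 against 3366 FPKM. EEF1A1 (15.4 against 545 FPKM) and GAPDH (18.7 against 2.39 FPKM), chosen after their values were seen, are uncertain because rows described as pseudogenes held 21.2% of all FPKM in estrus and 31.2% in diestrus and can share their reads.

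Across all 8269 counted genes 2590 were at least 2-fold higher in estrus, 2740 were at least 2-fold lower and 2939 lay within 2-fold, so 48.6% of the genes apart were higher in estrus. The median log2 ratio was -0.02 (95% interval -0.08 to 0.05 from order statistics over genes), and the SD over genes was 2.23. Genes are not independent replicates, and the correlation across the 6832 counted genes above 0 in both libraries was r = 0.657. The split depended on scaling and on expression. The share higher in estrus was 37.4% with equal sums after the 20 leading genes of each library were left out. It was 61.7% at a mean of at least 10 FPKM and 71.7% at a mean of at least 100 FPKM, a limit not among the alternatives set before.

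The authors' deposited table gave a p-value under 1 to 1253 genes and called 49 of them changed, 17 higher and 32 lower in estrus. These calls match an unadjusted p-value threshold of 0.05, at which 62.65 of these 1253 genes would be called if p-values were uniform. The q-values match 1292 tests, so the table does not show all tested genes with a p-value under 1. By the authors' q-values no gene reached 0.05, and TIMP1 was closest. CSPG5 had the next smallest p-value, 0.00455, with a q-value of 0.413. Of the called genes 27 were at 0 in estrus, 12 were at 0 in diestrus and 10 were above 0 in both, among them KRT6A, PPARGC1A and ATP6 with the authors' p-values of 0.0315, 0.0432 and 0.0138. The deposited p-values come from 1 library per stage and so rest on the spread that the authors' tool assumed.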

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

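The settings with a mean of at least 50 FPKM and without keratins were chosen after the results had been seen, and the others were fixed before. The oral squamous epithelium, mitochondrially encoded and cell proliferation lists stayed on their side of the random range under every setting that left at least 3 counted genes. Of 70 values of the 6 lists outside the range, 62 kept their placement, 7 moved inside and 1 turned direction. With a pseudocount of 10, 1412 genes were higher and 976 lower, neutrophils moved inside at percentile 7.66, and the salivary gland (99.0), heat shock (1.63) and respiratory chain (97.6) lists moved outside. With a pseudocount of 0.1 the lymphocyte list was at 97.85. Without a filter the median ratio was -0.16, neutrophils were at 28.98 and lymphocytes at 99.3. At a mean of at least 10 FPKM, 1519 genes were higher and 942 lower, the median was 0.51, estrogen-responsive genes were at 10.1, MHC genes at 7.50 and interferon-stimulated genes at 99.9. Among genes with an authors' p-value under 1, 570 were higher and 276 lower, the median was 0.81 and 3 lists lay outside. At a mean of at least 50 FPKM, 591 were higher and 284 lower, the median was 0.70 and 3 lists lay outside. Among genes above 0 in both libraries 1773 were lower, the median was 0.13, estrogen-responsive genes reversed to percentile 68.9, MHC genes were at 5.04 and heat shock genes at 1.67. At 4-fold, 1391 genes were higher and 1531 lower, fewer by construction. With unmatched random lists neutrophils were at 3.18 and the respiratory chain at 99.0, and with the mean of each list neutrophils were at 11.3 and lymphocytes at 99.55. Filters lower the counts by leaving out genes, while the cause of the other moves was not tested. For the estrogen-responsive and MHC lists, the limit to genes above 0 in both libraries left out only members at 0 in estrus. Equal upper quartiles moved the median ratio to -0.27 and equal sums without the leading genes moved it to -0.49, and the 6 lists kept their placement. At a q-value of at most 0.01 the authors' table calls 0 genes higher and 0 lower. At the authors' own threshold it calls 5 higher and 5 lower among genes above 0 in both libraries. Of 152 values of 38 named genes, 101 stayed within 1.5 times, 50 moved by more and kept their sign, and FTH1 reversed to -0.019 with equal upper quartiles. No row held several symbols, so leaving such rows out changed nothing. No paired analysis was possible because each stage has 1 library. At 1.25 FPKM per fragment and kb, the diestrus library limits the low genes most.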

Other observations

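The tests of explanations in this part, and the glycolysis, metallothionein, S100, keratin and further connective tissue groups, were chosen after the values had been seen, while the matrix, gland, epithelial and ribosomal protein lists were fixed before. Genes of glycolysis, the pathway that breaks glucose down to pyruvate and lactate, were higher in the estrus library, counted together with the glucose transporter SLC2A1. Of 18 counted genes 12 were at least 2-fold higher, 2 lower and 4 between, with a median log2 ratio of 1.72, in a group put together after the values were seen. LDHA stood at 2800.4 against 436 FPKM, TPI1 at 2291 against 313 FPKM, PKM at 1554 against 439 FPKM and PGK1 at 615 against 83.2 FPKM, while ALDOA stood at 375 against 661 FPKM. Abundant genes leaned towards estrus as a whole, with a median log2 ratio of 0.77 over all genes with a mean of at least 100 FPKM. The glycolysis group shares PGK1 and GAPDH with the reference genes, and the values of GAPDH are uncertain, as given above.

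All 3 counted metallothioneins, small proteins that bind zinc and copper, were higher in estrus, with MT2A at 20731 against 1084 FPKM and MT1E and MT1A at 15.8 and 8.13 FPKM in estrus and at 0 in diestrus. The calcium-binding S100 genes were divided, with 5 of 10 higher, 3 lower and 2 between. S100A4, found in fibroblasts and other motile cells, stood at 14005 against 689 FPKM and S100A10 at 2462 against 428 FPKM, while S100A16 stood at 33.8 against 169 FPKM. Pseudogene rows on chromosome 23 were listed at 2607 FPKM (ENSBTAG00000031766), 2482 FPKM (ENSBTAG00000031773) and 514 FPKM (ENSBTAG00000031770) in estrus and at 0 in diestrus.

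Of 25 counted keratins 23 were at least 2-fold lower in estrus and 16 of these were listed at 0 there, while KRT6A was higher. A shift of reads among the 30 rows of its cluster on chromosome 5 at an unchanged total is argued against. These rows summed to 30489 FPKM in estrus and 1406 in diestrus, a ratio of 21.7. KRT6A itself held most of the estrus sum, and the other rows held 442.66 FPKM. Which keratin the reads under KRT6A came from was not checked, so wrongly assigned reads are not excluded. Less RNA of epithelial cells in the estrus library would not account for KRT6A. Of the 6 other epithelial genes with a mean of at least 10 FPKM, 2 lay above all 16 keratins other than KRT6A. They were S100A2 and S100A14, and the highest of these keratins of that mean was KRT25 at -0.32. Above the 15 lower keratins, the highest at -2.43, lay 4 of the 6, so the outcome turned on KRT25. KRT25 is not a counted member of the oral squamous epithelium list. The reference set was not limited to keratins of that list and was chosen after the values were seen. For the lower keratins, the comparison therefore does not tell less RNA of epithelial cells apart from other causes. A change of keratin use with the stage and a change in the kind of cells shed also remain open.

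Among 697 genes over 100 FPKM in diestrus 34, or 4.88% (exact 95% interval 3.40 to 6.75%), were listed at 0 in estrus, against 14 of 879, or 1.59% (0.873 to 2.66%), in the opposite direction. Of these 48 genes 46, or 95.8% (85.7 to 99.5%), have loci long enough for at least 10 expected fragments in either library. The exceptions are RPS29 and PRM3. At 100 FPKM 125 effective bp were enough, so locus spans nearly always pass and the interval adds little. A locus is only an upper limit of the transcript's length. Counting error is therefore argued against only for transcripts of at least that effective length. Of 23 ribosomal protein genes over 100 FPKM in either library 1, RPS29, was at 0 in the other (4.35%, interval 0.110 to 21.9%), against 4.28% of all 1122 such genes, which does not decide on failed estimates. With so few ribosomal genes, failed estimates and a difference between the samples cannot be told apart, and an effect of the stage was not tested.

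All 25 matrix genes were above 0 in both libraries, whereas 23 of 26 gland genes were at 0 in both, 88.5% (exact 95% interval 69.8 to 97.6%). Low depth was not excluded for gland transcripts of low level. Zeros were less frequent among ribosomal protein genes, of which 32.9% (22.9 to 44.2%) were at 0 in both, whatever their cause. Of 35 connective tissue genes outside the matrix list 85.7% (69.7 to 95.2%) were above 0 in both libraries, against 35.1% of all rows. SERPINH1 stood at 1064 against 1217 FPKM and CTSK at 2682 against 1392 FPKM. All rows include 4910 pseudogene rows, and only 3 of 30 heat shock and chaperone rows were at 0 in either library. The share is thus not particular to connective tissue genes and cannot tell which cells the RNA came from. Whether the RNA of matrix and connective tissue genes came from saliva, from tissue shed into it or from another library was not tested.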
